A study of Homo sapiens with 29 samples.

How the data were processed

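The labels describe 29 libraries in 14 groups. They cover INO80, MCRS1 and RUVBL2 in HepG2 and Huh7 cells, RUVBL1 in HepG2, YY1 in Huh7, input in both lines, and acetylated histone H3 lysine 27 with input in HepG2 cells given EPZ-6438 or DMSO. No sample record describes YY1 in HepG2, whose peaks come from ENCODE reads put through the same steps, per the series description. Each library's group was taken from its title. Nothing in the labels says that libraries of a group came from separate cultures, so the spread between them may be technical in part.

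The submitters' processing notes name Bowtie2, SAMtools, MACS2, bedtools and deepTools, with the builds hg19 and dm3, and no versions. The authors deposited 1 peak list per factor and line, already filtered, with 6 columns that give positions only. Whether peaks were called per library or on pooled libraries is not given in the sources used here, and INO80 in HepG2 had 3 libraries where the other groups had 2. A factor's replicates could therefore not be compared, and the number of peaks may follow the depth of a library as well as occupancy. The other table holds the count of fly tags per library, as the authors deposited it, with reads of the fly spike-in aligned to dm3 per the labels. Those counts were used without scaling. Input libraries were not analysed here on their own.

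Peaks counted as overlapping when they shared at least 1 bp. The chance level came from moving the second list along each chromosome by a random amount, with peaks that pass the end wrapped to its start, in 1000 shifts with a fixed seed. The p is one-sided and its smallest value is 0.000999. Values of p were adjusted by the Benjamini-Hochberg method within each family of tests, and the threshold on the adjusted p was 0.05. Shares have 95% Wilson intervals. Differences of shares and odds ratios have intervals or errors from 1000 bootstrap draws over blocks of 10 Mb, because neighbouring peaks are not independent. The intervals of motif content and of the downstream share of wide peaks came from draws of single windows or peaks. They do not cover that dependence. INO80 peaks with and without YY1 were compared by Fisher's exact test (two-sided) for shares and by 100000 permutations for log2 width, and paired partner shares by an exact McNemar test. Where those p-values fell below what the computer can hold, intervals are given in their place. Values for the HepG2 and Huh7 odds ratios were compared by their block errors with a normal approximation. Fly tags were compared on the log2 scale by an exact permutation test (two-sided), which has 6 arrangements.

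Gene starts came from GENCODE release 44 lifted to GRCh37, which is the sequence of hg19. A gene was called bound when a peak lay within 1 kb of a start of any of its protein-coding transcripts in the GENCODE basic set. The background was 19785 protein-coding genes. The 11 gene lists were written before the data were examined and hold 496 entries, of which 458 matched the annotation as written, 37 matched through an older symbol and 1 did not match. The lists are the INO80 complex subunits, cytosolic ribosomal proteins, mitochondrial respiratory chain, DNA replication, DNA repair, HOX genes, developmental regulators often held by Polycomb, hepatocyte genes, replication-dependent histones, neuronal genes and blood cell genes. Each list was tested in each of the 9 peak lists by Fisher's exact test (two-sided), which makes 99 tests adjusted together. All coordinates are 1-based on hg19.

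The rule for named genes, fixed beforehand, took for each line the 10 strongest INO80 peaks with YY1 and the 10 strongest without, the 5 strongest peaks of every other list, every INO80 subunit gene, and the 3 strongest members of each further gene list that passed its test. It ranked peaks by enrichment, which the lists do not hold, so width took its place and the centre of a peak took the place of its summit. Where no coding start lay within 1 kb, a peak was named by the genes it overlaps. The planned comparison of peak enrichment between INO80 peaks with and without YY1 became a comparison of width.

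Settings fixed beforehand asked for at least 50% of the first peak covered, a chance level from shifts of 50 to 500 kb or from regions with a peak of any factor in the other line, autosomes only, starts within 5 kb, starts of all annotated genes, genes with a peak in the other line as background, a replicate block, and each fly-tag library left out in turn. Those that needed enrichment or summits could not be run, nor could tags relative to human reads or input, which the table does not hold. Added after the data were seen were centres within 250 bp, the wider 50% of each list, the 3322 widest peaks of each list, every peak set to 200 bp about its centre, quintiles of INO80 peak width with a Mantel-Haenszel odds ratio, and all values without chromosomes 2, 14, 16, 17 and 20, of which HepG2 is known to carry extra copies.

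For the closing tests, windows of 500 bp about the centres of INO80 peaks were searched on both strands for the YY1 motif AANATGGCG and the shorter ATGGCGGC, with control windows moved by 10 kb for distal peaks and at coding starts without INO80 or YY1 for promoter peaks. The code was also tested on simulated data, some of them built on the peaks and bound genes of these lists. Overlaps planted at 10% and 70% of 23665 peaks were found at 11.6% and 70.4%, against 1.80% with none planted. Unrelated lists of 3000 randomly placed peaks were called in 3% of 200 draws. Such lists do not gather at promoters as the real ones do, so that rate may not hold for them. Gene lists whose odds of being bound were raised 2, 4 and 8 times among 19785 genes were called in 35.0%, 87.7% and 96.5% of draws, and unchanged lists in 0.273%. Those calls were adjusted over the 11 lists alone and not over 99 tests. A motif planted in 5% of 2000 windows was found in 6.55% and one planted in none in 1.05%. A planted log2 odds ratio of 1.5 came back as 1.49 within simulated strata, which stood in for quintiles of width. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, numba 0.67.0 and matplotlib 3.10.9.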

Results

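Occupancy of the INO80 chromatin remodelling complex was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in 2 human liver cancer cell lines, HepG2 and Huh7. INO80 is the ATPase that gives the complex its name and slides nucleosomes. MCRS1 is a subunit of the complex, RUVBL1 and RUVBL2 are ATPases it shares with other chromatin complexes, and YY1 is a sequence-specific transcription factor that binds DNA both with the complex and apart from it. INO80 was mapped from 3 libraries in HepG2 and 2 in Huh7, MCRS1 and RUVBL2 from 2 libraries per line, RUVBL1 from 2 in HepG2 only and YY1 from 2 in Huh7. The labels also give 2 input libraries for each line. For YY1 in HepG2, public ENCODE reads were passed through the same processing, and their number of libraries is not given. A further 8 libraries come from HepG2 cells given EPZ-6438, an inhibitor of the histone methyltransferase EZH2, or the solvent DMSO, with 2 libraries each of acetylated histone H3 lysine 27 and of input.

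The 9 peak lists give positions on hg19 and neither a height nor an enrichment, so the read depth behind a peak is unknown and peak width stands in for its strength. Each factor has 1 list per line, so no value taken from peaks has a replicate error, and the intervals below cover the number of peaks or genes counted. In HepG2 the lists hold 23665 INO80 peaks (median width 666 bp), 23425 MCRS1 peaks (658 bp), 5518 RUVBL1 peaks (279 bp), 12936 RUVBL2 peaks (335 bp) and 39293 YY1 peaks (287 bp). In Huh7 they hold 15303 INO80 peaks (438 bp), 6020 MCRS1 peaks (273 bp), 3322 RUVBL2 peaks (254 bp) and 21554 YY1 peaks (391 bp). INO80 peaks covered 22.4 Mb of the genome in HepG2 and 10.1 Mb in Huh7.

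The widest peaks of the partners show where they covered the longest stretches. ALB, the gene of serum albumin, carried an MCRS1 peak of 15648 bp in HepG2 (chromosome 4, 74269990 to 74285637). A RUVBL1 peak of 9316 bp lay within APOB, which encodes the main protein of low-density lipoprotein, and the widest YY1 peak in HepG2 covered 12322 bp at IGF2, the gene of an insulin-like growth factor (chromosome 11, 2149496 to 2161817). SLC16A3, a lactate transporter gene, was covered by the MCRS1 peak of 19091 bp and the RUVBL2 peak of 13350 bp in HepG2. In Huh7 the widest MCRS1 peak covered 7039 bp at the non-coding RNA gene MALAT1, the widest RUVBL2 peak 13328 bp over MIDN and CIRBP, and the widest YY1 peak 38438 bp over the array of 5S ribosomal RNA genes (chromosome 1, 228744053 to 228782490). The same array held the widest MCRS1 peak in HepG2, of 19448 bp. Its genes are near-identical copies, so reads placed there cannot be assigned to 1 copy with certainty.

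The co-occupancy of the factors in HepG2 asks how often the subunits and YY1 are found on the same DNA. INO80 shared most of its sites with MCRS1 and with YY1, and fewer with the RUVBL ATPases. Of the 23665 INO80 peaks, 70.4% overlapped an MCRS1 peak, 70.3% a YY1 peak, 41.1% a RUVBL2 peak and 18.8% a RUVBL1 peak. Seen from the partner, 88.9% of RUVBL1 peaks, 81.3% of RUVBL2 peaks, 71% of MCRS1 peaks and 44.4% of YY1 peaks overlapped INO80. Partner lists shifted along each chromosome gave 1.93% for MCRS1, 2.36% for YY1, 0.951% for RUVBL2 and 0.362% for RUVBL1. The observed INO80 shares were thus 36.4, 29.8, 43.2 and 52.0 times the shifted ones. Each of the 20 ordered pairs in HepG2 had p = 0.000999 in the circular-shift permutation test (one-sided), which is the smallest p that 1000 shifts can give, and the same value after Benjamini-Hochberg adjustment. The size of the excess depends on the chance level: INO80 with YY1 gave 15.4 with shifts of only 50 to 500 kb and 1.34 among regions that hold a peak of any factor in Huh7. The shares also follow the length of the lists: RUVBL2 lay 29.3 points below YY1 over all peaks and 1.84 points below it over the 3322 widest of each list.

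In Huh7 YY1 was the partner found most often at INO80 peaks. YY1 overlapped 69.0% of the 15303 INO80 peaks, MCRS1 31.8% and RUVBL2 17%. Of the RUVBL2 peaks 95% overlapped YY1, 80.7% INO80 and 55.6% MCRS1. Of the MCRS1 peaks 85.5% overlapped INO80, and of the YY1 peaks 47.8%. The INO80 shares were 62.2 times the shifted lists for YY1, 120.0 times for MCRS1 and 94.9 times for RUVBL2. The 12 ordered pairs in Huh7 again had p = 0.000999, the smallest the permutation test by shifts can give. INO80 with YY1 gave 29.7 with the short shifts and 2.55 among regions with a peak of any factor in HepG2.

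**Figure D1:**
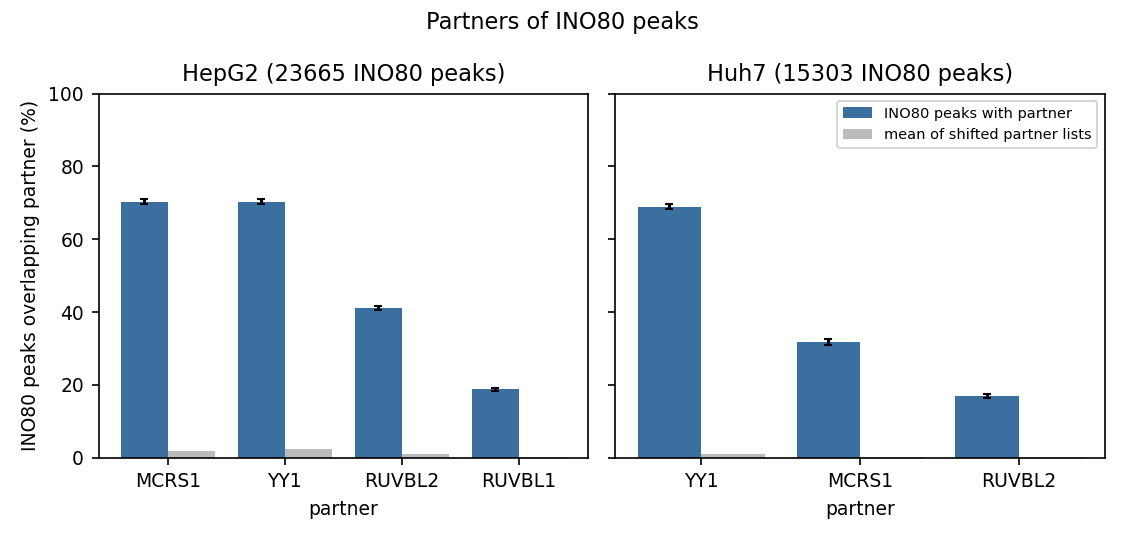
Share of INO80 peaks (percent, vertical axis) that overlap a peak of each partner in HepG2 and Huh7, as observed (blue, with 95% Wilson intervals) and as the mean of shifted partner lists (grey). YY1 overlaps 70.3% of INO80 peaks in HepG2 and 69.0% in Huh7, and MCRS1 70.4% and 31.8%.

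Within a line, the partner shares can be set against each other on the same INO80 peaks. In HepG2 MCRS1 and YY1 were found about equally often: the difference was 0.00423 percentage points (95% block interval -0.857 to 0.829), with 1822 INO80 peaks holding MCRS1 alone and 1821 holding YY1 alone of the pair. In Huh7 the MCRS1 share was lower than that of YY1, with a difference of -37.2 points (-38.4 to -35.9), which shrank to -6.47 points over the 3322 widest peaks of each list. The HepG2 difference does not keep 1 direction across settings: it was -5.81 points over the wider 50% of each list and 11.6 points over the 3322 widest peaks.

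To ask which sites are held in both lines, each factor was compared between HepG2 and Huh7. For every factor most Huh7 peaks overlapped one in HepG2, and fewer HepG2 peaks overlapped one in Huh7. Of the HepG2 INO80 peaks 44.2% overlapped an INO80 peak in Huh7, and 74.4% of the Huh7 peaks overlapped one in HepG2. The shares were 35.9% and 65.8% for YY1, 19.8% and 82.9% for MCRS1, and 18.3% and 73.6% for RUVBL2. Measured in base pairs as the Jaccard index, the shared length was 0.307 of the joint length for INO80, 0.290 for YY1, 0.132 for RUVBL2 and 0.0966 for MCRS1. All 8 comparisons had p = 0.000999, the smallest the permutation test allows. MCRS1 and RUVBL2 lists were several times shorter in Huh7, and no list gives the depth it was called at.

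INO80 peaks with YY1 were then compared with INO80 peaks without it, the question being whether the complex also sits at sites of its own. Among the widest HepG2 peaks with YY1, ALB led with 15541 bp (chromosome 4, 74269989 to 74285529), followed by SETD1B, a histone H3 lysine 4 methyltransferase gene (14809 bp), and IRF2BP2, a transcriptional corepressor gene (14721 bp). FGL1, which encodes a secreted liver protein, SLC38A2, an amino acid transporter gene, and the non-coding RNA genes NEAT1 and MIR21, the last within VMP1, were also among the 10 widest. All 10 held MCRS1 and RUVBL2. The widest peaks without YY1 covered or lay next to EN1, a homeobox gene of the midbrain and limb (8686 bp, chromosome 2, 119602373 to 119611058), SKOR1, a corepressor gene of the nervous system (7624 bp), NFATC1 (7524 bp), NKX2-2, a homeobox gene of the neural tube and the islet (7297 bp, chromosome 20, 21488094 to 21495390), LHX4, a homeobox gene of the pituitary (7258 bp), PDGFA, MN1 and UNCX. The narrowest of the 10, of 5505 bp, overlapped PTPRN2 and lay 332710 bp from the nearest coding start. None of these 10 held RUVBL1 or RUVBL2, and MCRS1 was present at 3 of them, at NKX2-2, PDGFA and UNCX.

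**Figure D2:**
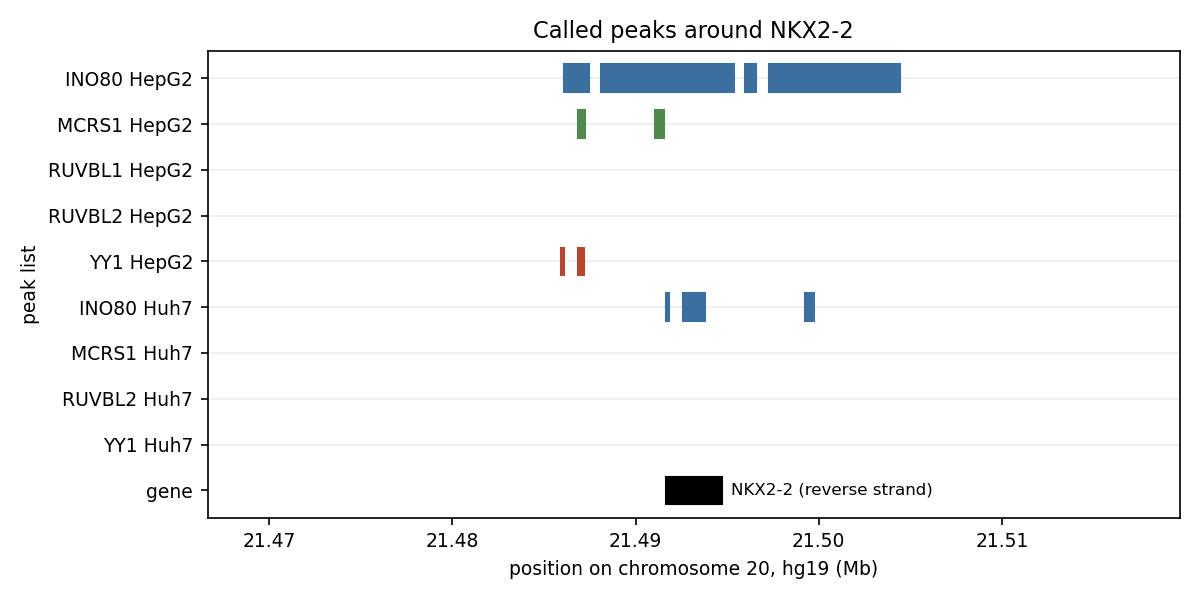
Called peaks (bars, one line per list) around NKX2-2 on chromosome 20, by position in Mb on hg19, with the gene as a black bar. INO80 covers the gene in HepG2 with a peak from 21488094 to 21495390 and has shorter peaks there in Huh7. The YY1 peaks of HepG2 end at 21487205, past the end of the gene, which lies on the reverse strand. They overlap a separate HepG2 INO80 peak from 21486096 to 21487444. No YY1 peak is seen in Huh7.

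In Huh7 the widest peaks with YY1 were at TNRC18 (10666 bp), MALAT1 (10026 bp), PDGFA, NEAT1, ACTB, SLC29A2, SNHG29, RCC1 with SNHG3, TGIF1 and GAPDH. Without YY1 they were LHX4 (7128 bp, chromosome 1, 180197865 to 180204992), RFX4, a transcription factor gene of the developing brain (5084 bp), FLRT2, LRRC26 with GRIN1, DHH, FIBCD1, HRK, SIM2, a region near no coding start on chromosome 6, and HELT. None of these 10 held MCRS1 or RUVBL2, and all 10 overlapped an INO80 peak in HepG2. PDGFA, the gene of a platelet-derived growth factor chain, held YY1 under its INO80 peak in Huh7 and none under that in HepG2.

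Across all peaks, the other subunits followed YY1. In HepG2 MCRS1 was present at 89.1% of the 16648 INO80 peaks with YY1 and at 26.0% of the 7017 without, a log2 odds ratio of 4.54 (95% block interval 4.43 to 4.66). RUVBL2 was present at 54.6% and 9.15% (3.58), and RUVBL1 at 25.2% and 3.58% (3.18). In Huh7 MCRS1 was present at 42.5% of the 10552 INO80 peaks with YY1 and at 7.96% of the 4751 without (3.10, 2.87 to 3.30), and RUVBL2 at 24.2% and 0.926% (5.09, 4.56 to 5.76). INO80 peaks with YY1 were wider, with medians of 851 against 261 bp in HepG2 and 552 against 260 bp in Huh7. The mean log2 difference in width was 1.11 and 0.77, each with p = 1e-05, the smallest that 100000 permutations can give. Wide peaks meet other peaks more often by chance. With every peak set to 200 bp about its centre, the log2 odds ratio was 2.37 for MCRS1 and 1.46 for RUVBL2 in HepG2, 1.48 and 1.20 in Huh7, and the log2 width difference fell to 0.17 and 0.20.

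**Figure D3:**
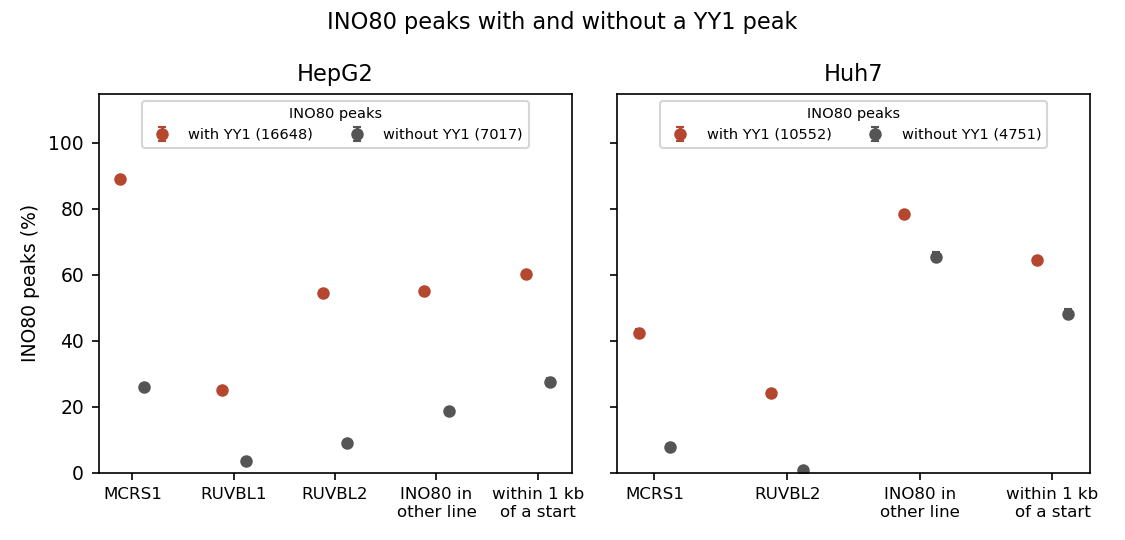
Share of INO80 peaks with YY1 (red) and without YY1 (grey) that overlap each other subunit, overlap INO80 in the other line, or lie within 1 kb of a coding gene start (percent, vertical axis, with 95% Wilson intervals), in HepG2 and Huh7. MCRS1 is found at 89.1% against 26.0% in HepG2 and at 42.5% against 7.96% in Huh7.

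Sites with YY1 were also more often held by INO80 in the other line. Of the HepG2 INO80 peaks 55.0% with YY1 and 18.8% without overlapped INO80 in Huh7, a log2 odds ratio of 2.40 (2.28 to 2.53), which was 1.58 within quintiles of INO80 peak width and 0.57 over the 3322 widest peaks of each list. Of the Huh7 peaks 78.4% and 65.5% overlapped INO80 in HepG2 (0.94, 0.79 to 1.06), a value that was 0.32 within the quintiles. At the 10471 HepG2 INO80 peaks shared with Huh7, YY1 was present in both lines at 7440, in HepG2 alone at 1715, in Huh7 alone at 432 and in neither at 884, so the YY1 state of a site in 1 line went with that in the other (log2 odds ratio 3.15, 95% block interval 2.94 to 3.37; 1.70 with peaks set to 200 bp and 4.14 over the wider 50% of each list).

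Peaks were next placed against the starts of protein-coding genes. INO80 and its partners lay at promoters far more often than their shifted lists in both lines. Within 1 kb of a start lay 50.6% of INO80, 46.2% of MCRS1, 52.3% of RUVBL1, 55.6% of RUVBL2 and 30.6% of YY1 peaks in HepG2, and 59.5% of INO80, 64.4% of MCRS1, 66.7% of RUVBL2 and 44.4% of YY1 peaks in Huh7. Shifted lists gave 2.10% to 2.57%, and each list had p = 0.000999, the smallest the permutation test allows. INO80 was found at 12606 of 19785 coding genes in HepG2 and at 9436 in Huh7. INO80 peaks with YY1 were at promoters in 60.2% of cases against 27.7% without in HepG2 (log2 odds ratio 1.99, 1.87 to 2.09), and in 64.5% against 48.3% in Huh7 (0.96, 0.83 to 1.10). Within quintiles of width the values were 1.21 and 0.65, and over the 3322 widest peaks of each list they were 0.58 and, with the Huh7 call ended, 0.13 (Fisher's exact test, adjusted p = 0.281).

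Gene lists fixed before the data were examined were set against all other coding genes. INO80 was at 63.7% of all coding genes in HepG2 and at 47.7% in Huh7. INO80 occupied the starts of most listed genes of cytosolic ribosomal proteins, the respiratory chain, histones, DNA replication and DNA repair in both lines. The same lists were called higher for MCRS1 and YY1 in both lines, so they are not particular to INO80. Few genes of other cell types held INO80. All 77 genes of cytosolic ribosomal proteins were bound in each line, the widest peaks being at RPS2, RPS12 and RPLP0 in HepG2 and at RPS2, RPL3 and RPL13A in Huh7. Of 47 genes of the mitochondrial respiratory chain 46 were bound in HepG2 (Fisher's exact test, adjusted p = 8.38e-08) and 42 in Huh7 (1.71e-08), led by NDUFB10 of complex I and UQCRH of complex III in HepG2 and by ATP5PF and CYC1 in Huh7. Of 40 DNA replication genes 37 and 35 were bound, with RRM2, which supplies deoxynucleotides, POLE and ORC6 widest in HepG2 and MCM5, MCM7 and FEN1 in Huh7. Of 40 DNA repair genes 38 and 31 were bound, with FANCA, BRCA1 and MSH6 widest in HepG2 and MDC1 and BRCA1 in Huh7. Replication-dependent histone genes, which lie in dense clusters so that 1 peak can reach several, were bound at 26 and 27 of 27, with H2AC6 and H3C4 widest in both lines.

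Genes of other cell types were bound less often than the rest of the genome. Of 30 neuronal genes INO80 was at 10 in HepG2 (Fisher's exact test, adjusted p = 0.00163) and 7 in Huh7 (0.0129), the widest peaks being at GAD1, TUBB3 and GRIN2A. Of 30 blood cell genes it was at 8 (0.000154) and 6 (0.00414), among them HBA1, LYZ and IKZF1 in HepG2 and CD68, KIT and CD14 in Huh7. Hepatocyte genes were not called apart, with 36 of 54 bound in HepG2 (0.785) and 18 in Huh7 (0.051). INO80 was at 19 of 39 HOX genes, the homeobox genes of the body axis, in HepG2 (0.0781) and 16 in Huh7 (0.436), and at 65 and 41 of 95 developmental regulators that Polycomb often holds (0.413 and 0.426). For those lists the partners gave lower shares than the rest of the genome: MCRS1 was at 4 HOX genes in HepG2 and 1 in Huh7, YY1 at 9 and 12, and at developmental regulators MCRS1 was at 27 and 9 and YY1 at 26 and 28, the adjusted p lying at or under 0.0136 in all 8 tests. Both background and annotation matter here. The starts of all annotated genes add non-coding genes and pseudogenes, and also further transcripts of the listed genes. With them no list was called lower for INO80 or MCRS1. The log2 odds ratio of HOX genes with INO80 then turned from -0.89 to 1.75 in HepG2 and from -0.39 to 1.87 in Huh7. Against the coding genes with a peak of any factor in the other line, 1 list, the ribosomal proteins, stayed higher for INO80 in HepG2. HOX genes went the other way there, to -2.84, and were called lower. Developmental regulators gave -0.99 in HepG2 and -0.89 in Huh7, the last past the threshold.

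**Figure D4:**
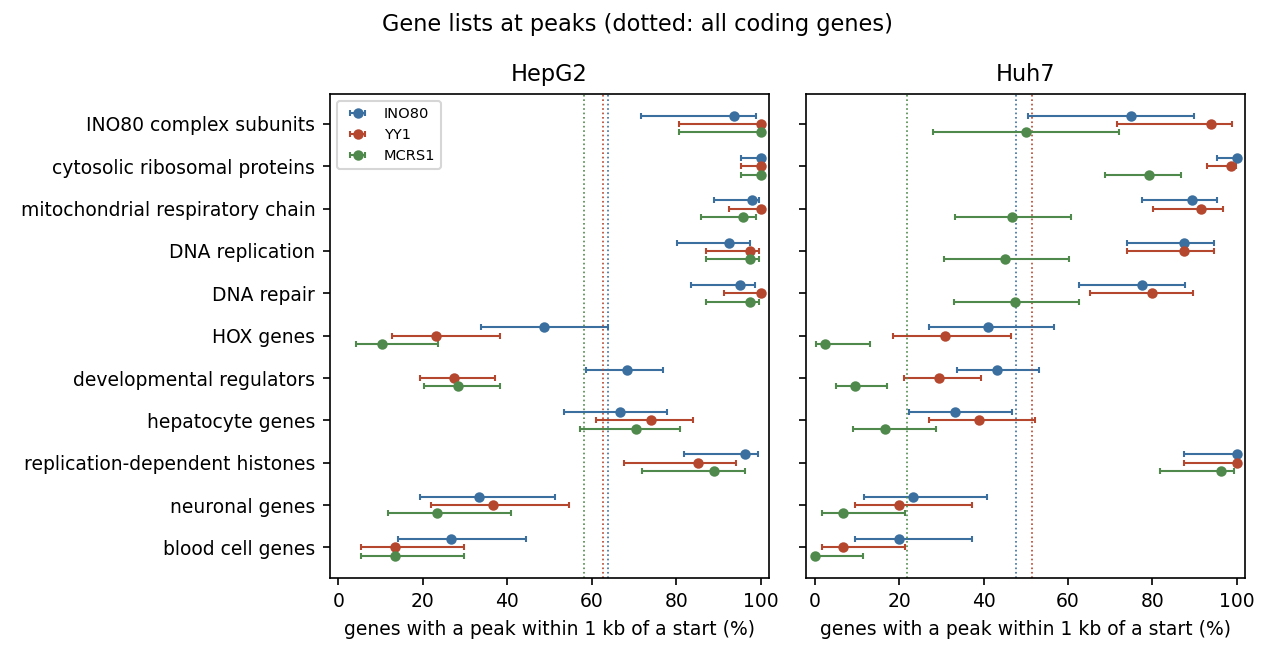
Share of each list's genes with a peak of INO80 (blue), YY1 (red) or MCRS1 (green) within 1 kb of a start (percent, horizontal axis, with 95% Wilson intervals) in HepG2 and Huh7, with dotted lines at the share over all coding genes. INO80 is at all 77 ribosomal protein genes in each line, and at 65 of 95 developmental regulators in HepG2, where MCRS1 is at 27 and YY1 at 26.

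Most genes of the complex itself were bound by INO80, as were 63.7% of all coding genes in HepG2 and 47.7% in Huh7. Against coding genes with a peak of any factor in the other line, their HepG2 log2 odds ratio was 0.20, not past the threshold. In HepG2 INO80 was at 15 of the 16 subunit genes (Fisher's exact test, adjusted p = 0.0207), INO80, INO80B, INO80C, INO80D, INO80E, ACTR5, ACTR8, ACTL6A, ACTB, YY1, MCRS1, RUVBL1, UCHL5, NFRKB and TFPT, with RUVBL2 the exception. In Huh7 it was at 12 (0.0529, not past the threshold), where ACTR5, ACTR8 and NFRKB were also without a peak. The widest of these peaks lay at ACTB, with 9818 bp in HepG2 and 6216 bp in Huh7. YY1 was at all 16 in HepG2 and at 15 in Huh7, all except NFRKB.

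The remaining table holds tags of fruit fly chromatin, which the submitters added to each immunoprecipitation so that libraries can be scaled to one another. Libraries of acetylated histone H3 lysine 27 from DMSO-treated HepG2 cells gave 1644727 and 1565449 fly tags, and those from cells given 1.0 µM EPZ-6438 for 120 h gave 803332 and 781292. The mean difference, EPZ-6438 minus DMSO, was -1.02 on the log2 scale (SE 0.04, 2 libraries in each group), larger than the spread between replicates in either group. The exact permutation test (two-sided) gave p = 0.333, which is the smallest that 2 against 2 libraries can reach. The table gives no human read totals, so the tags stand without the depth of their libraries.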

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

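Among the tests below, the one of extra chromosome copies and those of the YY1 motif at promoter and distal peaks apart and of INO80 peaks with neither YY1 nor MCRS1 were chosen only after their results had been seen, as were the comparisons of odds ratios between the lines and the settings named with them.

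The link between YY1 and the other features of INO80 peaks differed between HepG2 and Huh7 in 4 comparisons, each with a 95% interval of the difference that excludes 0. The log2 odds ratio of MCRS1 at INO80 peaks with against without YY1 was 4.54 in HepG2 and 3.10 in Huh7, a difference of 1.44 (95% interval 1.20 to 1.68) that ranged from 0.90 to 2.66 over the other settings. For an INO80 peak in the other line the difference was 1.47 (1.28 to 1.66), but over the 3322 widest peaks of each list it was -0.36. For a coding start within 1 kb it was 1.02 (0.85 to 1.19), and 0.42 to 1.01 over the other settings. The ranges over settings leave out the quintiles of INO80 peak width, for which no error was computed. For RUVBL2 the sign was the opposite, -1.52 (-2.16 to -0.87), and it turned to 0.38 with centres within 250 bp. The 2 lines differ in the number and width of peaks in every list, and YY1 in HepG2 comes from ENCODE reads. These differences can therefore carry the source of the YY1 reads and the calling of peaks as well as the cells. With 1 list per line, the intervals cover the peaks counted and not replicates of a line.

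INO80 peaks without a called YY1 peak number 7017 in HepG2 and 4751 in Huh7. If YY1 were bound there and missed, its motif would be as common as at INO80 peaks with YY1; measured from control windows to INO80 windows with YY1, motif content came 5.69% of the way in HepG2 (95% interval -10.2 to 19.2) and 5.20% in Huh7 (0.166 to 10.0). Taken apart, it came -4.60% of the way at HepG2 promoters (-9.45 to 0.707) and 3.23% at Huh7 promoters (-0.670 to 7.72). At distal Huh7 peaks it was 10.3% (-4.46 to 25.2). At the 5076 distal HepG2 peaks it was 58.3% (-71.0 to 337), which decides nothing. There the motif barely set windows with YY1 (2.49%) apart from control windows (1.95%), so the HepG2 value over all peaks rests mainly on promoters. The shorter motif ATGGCGGC gave 22% there (5.89 to 42.0) and 25.5% at distal Huh7 peaks (9.89 to 43.6). Most windows with YY1 lacked AANATGGCG too. It was in 8.12% at HepG2 promoters, 12.3% at Huh7 promoters and 5.53% at distal Huh7 peaks. If missed sites carry the motif as often as called ones, these values argue against missed YY1 as the whole cause. That covers promoters of both lines and distal Huh7 peaks, and distal HepG2 peaks by the shorter motif only. Missed sites that carry the motif less often than called ones stay open, since motif content cannot show them. If the INO80 calls were background at random places, MCRS1 would be there no more often than its shifted lists. It was there 16.7 times as often in HepG2 (15.6 to 17.7) and 39.3 times in Huh7 (34.0 to 46.1). Of the peaks with neither YY1 nor MCRS1, 19.7% in HepG2 and 65.2% in Huh7 overlapped INO80 in the other line. These shares were 27.5 (25.2 to 30.0) and 51.3 (49.7 to 52.9) times the shifted lists. These tests argue against background placed at random along a chromosome, for the peaks that hold MCRS1 or recur. Shifted lists do not keep to promoters, where many peaks of every list lie. The tests therefore cannot decide on background that gathers at promoters, is shared by the immunoprecipitations of a line or recurs in both lines. Such background, the rest of the peaks and a form of the complex that reaches DNA without YY1 stay open. No biological explanation was tested.

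Wide INO80 peaks over coding starts might follow transcription into gene bodies. Transcription was not measured, so the test took YY1 as its stand-in. Under such a spread, peaks of 2 kb or more with YY1 would lie at least 10 points further downstream of the start than those without. Only peaks over coding starts on a single strand entered, in HepG2 1536 with YY1 and 254 without, of 2527 that wide. In Huh7 394 and 55 of 667 entered. The HepG2 peak over ALB, of 15541 bp with YY1, had its start 7734 bp from its centre, close to an edge. The mean share of the peak downstream was 65.3% with YY1 and 64.3% without in HepG2, a difference of 0.999 points (95% interval -1.61 to 3.52), and 66.9% and 64.6% in Huh7, a difference of 2.31 points (-3.40 to 8.07). Both intervals lie under 10 points, so the peaks with and without YY1 that entered did not differ by that much. A spread along transcribed genes stays open, since transcription was not measured and peaks without YY1 may also lie over transcribed genes. No biological explanation was tested.

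Chromosomes 2, 14, 16, 17 and 20 held 30.5% of INO80 peaks in HepG2 and 23% in Huh7. The mean log2 excess over the other 17 autosomes was 0.58 for INO80, 0.62 for MCRS1, 0.54 for RUVBL2 and 0.29 for YY1, where extra copies in HepG2 would raise all factors, and across 22 autosomes the log2 ratio of HepG2 to Huh7 peak shares of INO80 went with that of YY1 (Pearson's r = 0.627, interval 0.280 to 0.830, permutation p = 0.00193, adjusted over 6 pairs of factors p = 0.00232; Spearman's rho = 0.648, permutation p = 0.0017). Without chromosomes 16 and 17, the farthest from the median, r was 0.687, and over the 17 other autosomes alone it was 0.548, so the correlation is not particular to the 5. The alternative that genes of these chromosomes are bound more often asks for the excess at promoters, but on the log2 scale it was 0.12 there and 0.99 at distal peaks, a difference of 0.87 (0.70 to 1.05). Extra copies stay open, since the interval of r reaches down to a weak correlation and no copy number was measured. Most INO80 peaks also overlap YY1 (70.3% in HepG2, 69.0% in Huh7). The ratios of INO80 and YY1 can thus move together whatever the cause, and r cannot decide on extra copies.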

How the results depend on the processing

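Of the settings here, centres within 250 bp, the wider 50% of each list, the 3322 widest peaks, peaks set to 200 bp, quintiles of width, the lists without chromosomes 2, 14, 16, 17 and 20, and centres of peaks at gene starts were chosen only after the data were seen. The settings planned on enrichment and on summits were not run, since the lists hold neither, nor were fly tags relative to human reads or input. Co-occupancy within a line and of the same factor between lines kept its direction and its call in all 160 values in HepG2, 96 in Huh7 and 56 between lines, with folds from 1.34 to 389 by setting, and so did promoter shares in all 18. No depth can be read from peak lists, so a weak site cannot be told from a shallow library. For fly tags, leaving out each library in turn gave -1.05 to -0.98, the linear scale -812776 and the replicate block -1.02 (exact p = 0.5, the smallest it allows); the lone library left in a group is assumed to vary like the other. With 2 libraries per group the pairing by replicate number could not be checked.

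MCRS1 minus YY1 at INO80 peaks in HepG2, 0.00423 points and not past the threshold, was 1.82 with centres, 2.96 with 200 bp peaks and 11.6 with the widest peaks, all past it, and reversed to -5.81 with the wider 50% and -2.28 without the 5 chromosomes. The promoter odds ratio of Huh7 INO80 peaks with YY1 was 0.13 over the widest peaks and no longer past the threshold. The line difference for RUVBL2 reversed to 0.38 with centres and 0.26 with 200 bp peaks and fell short of the threshold at -0.10 with the wider 50% and -0.25 with the widest peaks, and that for the other line to -0.36 with the widest peaks. The cause was not tested.

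Gene lists (log2 odds ratios) depended on the definition of a start and on the background, and the cause was not tested except where stated. Direction and call were kept in 334 values for single lists and their counts, 59 fell short of the threshold, 25 newly passed it, 27 reversed and 23 counts moved. Within 5 kb, INO80 at HOX genes reversed to 0.33 in HepG2 and 1.31 in Huh7, developmental regulators gave 1.09 in HepG2, now past the threshold, and reversed to 0.36 in Huh7, and neuronal genes gave -1.04 in Huh7, no longer past it. Hepatocyte genes reversed to 0.30 with MCRS1 and 0.60 with RUVBL2 in Huh7. Lists called lower were 1 for INO80 in Huh7, and for RUVBL2 in Huh7 5 lists were higher and 2 lower.

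With the starts of all annotated genes, the background gains non-coding genes and pseudogenes that hold few peaks, which raises coding lists by construction. The listed genes also gain the starts of their other transcripts, which can only add bound members. In HepG2 INO80 reversed to 1.75 at HOX, 0.44 at neuronal and 0.00627 at blood cell genes, and passed the threshold at developmental (2.42) and hepatocyte genes (2.23). In Huh7 INO80 reversed to 1.87 at HOX, 1.58 at developmental, 0.91 at hepatocyte and 0.80 at neuronal genes, gave 3.38 at subunit genes, now past the threshold, and -0.21 at blood cell genes, no longer past it. Other factors reversed at developmental regulators with MCRS1 (0.21 in HepG2, 0.19 in Huh7) and YY1 in Huh7 (0.57), at hepatocyte genes in Huh7 with MCRS1 (0.80), RUVBL2 (1.20) and YY1 (0.97), at neuronal genes with YY1 in HepG2 (0.76) and at HOX genes with YY1 in Huh7 (0.78). Lists called lower were 0 for INO80, MCRS1 and RUVBL2 in both lines and for RUVBL1 and YY1 in HepG2, and 1 for YY1 in Huh7. Lists called higher in Huh7 were 9 for INO80 and 6 for RUVBL2.

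With the centre of a peak in place of any overlap, developmental regulators reversed to -0.29 and hepatocyte genes to -0.80 for INO80 in HepG2, hepatocyte genes reversed to -0.38 for MCRS1, and in Huh7 hepatocyte genes gave -1.17 for INO80, now past the threshold.

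Against genes with a peak in the other line, fewer genes are tested. In HepG2 INO80 gave 0.20 at subunit, 1.85 at respiratory chain, 1.60 at replication, 1.52 at repair, 1.09 at histone and -1.29 at blood cell genes, none past the threshold any more, while HOX genes passed it at -2.84 and developmental regulators reversed to -0.99. In Huh7 INO80 gave 0.81 at repair, -1.17 at neuronal and -0.24 at blood cell genes, no longer past it, and -0.89 at developmental regulators and -1.39 at hepatocyte genes, now past it. RUVBL2 in HepG2 reversed to -0.0837 at replication genes, and YY1 in HepG2 to -0.58 at histone and 0.99 at neuronal genes. Lists called higher in HepG2 were 1 for INO80 and 2 each for MCRS1, RUVBL2 and YY1, and in Huh7 2 for MCRS1 and 3 for YY1. Lists called lower in HepG2 were 2 each for MCRS1 and RUVBL2 and 1 for RUVBL1.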

Other observations

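The comparison of partners at gene lists and its settings were chosen after the values had been seen.

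Where INO80 was bound at developmental genes, YY1 and MCRS1 were present less often than at other INO80-bound genes. In HepG2 INO80 held 65 developmental regulators and YY1 was at 24 of them (36.9%), against 89.3% of the other INO80-bound coding genes, a log2 odds ratio of -3.83 (Fisher's exact test, adjusted p = 3.1e-22). MCRS1 was at 26 of the 65 (40.0%), against 86.5%. INO80 without YY1 or MCRS1 was found for example at PAX2, PAX6, LHX2, SOX2 and NEUROG2, and with both for example at FOXA1, FOXA2, GATA4, GATA6 and TBX3, genes picked after their values were seen. In Huh7 YY1 was at 26 of 41 INO80-bound developmental regulators (63.4%), against 84.8% (-1.69, Fisher's exact test, adjusted p = 0.00279).

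HOX genes gave like values. In HepG2 INO80 was at 19 and YY1 at 6 of these (31.6% against 89.1% of other INO80-bound genes, log2 odds ratio -4.15, Fisher's exact test, adjusted p = 3.27e-08). In Huh7 YY1 was at 9 of 16 (56.2% against 84.8%, -2.12, Fisher's exact test, adjusted p = 0.0187) and MCRS1 at 1, HOXC10. Genes of a HOX cluster lie close together, so they are not independent. YY1 was also less frequent at the few INO80-bound genes of other cell types: in HepG2 at 6 of 10 neuronal genes (Fisher's exact test, adjusted p = 0.0401) and 4 of 8 blood cell genes (0.0187), and in Huh7 at 2 of 6 blood cell genes (0.0187), with 5 of 7 neuronal genes not called apart (0.379). MCRS1 in HepG2 was at 5 of those 10 (Fisher's exact test, adjusted p = 0.0187) and 4 of those 8 (0.0373). In Huh7 MCRS1 was not called apart, at 2 of 7 neuronal genes (Fisher's exact test, adjusted p = 0.788) and 0 of 6 blood cell genes (0.0821). In HepG2, then, the lack of partners is not particular to developmental genes. The same holds for YY1 in Huh7, where it rests on the 6 blood cell genes. In contrast YY1 was at all 77 INO80-bound ribosomal protein genes in HepG2 and at 76 in Huh7. All 12 values for YY1 at developmental regulators and HOX genes with starts within 5 kb, starts of all annotated genes or centres of peaks kept their direction and stayed past the threshold.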
